A study of Larimichthys polyactis and Larimichthys crocea with 36 samples.

How the data were processed

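RNA sequencing libraries were made from brain, liver and muscle of 4 kinds of fish: small yellow croaker (Larimichthys polyactis, LP), large yellow croaker (Larimichthys crocea, LC) and their 2 reciprocal hybrids, which the labels name LPC and LCP. There were 36 libraries in 12 groups of 3. The labels do not give the species of the mother of either hybrid, and no direction of cross is stated here. They also do not say whether the 3 libraries of a group came from separate fish, so p-values measure the spread between these libraries, which may in part be technical. Per the labels' protocols, total RNA was extracted with TRIzol, RNA of sufficient integrity was kept, mRNA was taken on oligo(dT) beads, and cDNA was primed with random hexamers and circularised. Such libraries read polyadenylated RNA, and no strand-marking step is described.

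The deposited table holds FPKM (fragments scaled by transcript length and by the library's total), which the authors computed, with 1 column per library and 2 decimals. Per the submitters' processing notes, reads passed through fastp. The aligner, the quantifier, the genome build and the annotation are not given in the sources used here. FPKM divides by gene length and by the library's total, so when a few transcripts take a larger part of a library, the values of all other genes fall without any change in their own number of molecules. The table lists 24212 gene identifiers (IDs). Of these, 21430 start with evm (here EVM IDs), 21317 of them carry 1 of 24 chromosome numbers and 113 do not. The other 2782 start with BGI_novel. The files do not pair these IDs with gene names, so no gene is named and only the IDs are printed. The chromosome number in an ID is part of its name. Positions were not used here. All value columns were mapped to a library by name.

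The sums of FPKM ranged from 492062 to 1029194 per library. They do not measure depth, and the number of fragments per library is unknown. Low values were examined for steps of 1 fragment by comparing each library with the first LP library of its tissue. The log2 ratio of the lowest values fell most often between -0.175 and 0.125 in brain, -0.325 and -0.025 in liver, and -0.075 and -0.025 in muscle. The fullest bin, 0.05 wide, held 17.7% to 63.3% of the IDs compared in brain, 16.9% to 31.7% in liver and 5.94% to 15.8% in muscle. Whole fragments were not recovered from this, and no count test was run.

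Each tissue was fitted by itself with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with the 4 crosses as groups, a mean-variance trend, 2-sided tests and Benjamini-Hochberg adjustment per contrast. An ID was called at an adjusted p under 0.05. IDs entered a tissue's fit with an FPKM of at least 1 in at least 3 of its 12 libraries, which gave 17931 in brain, 12553 in liver and 10847 in muscle. All fold changes are on the log2(FPKM + 1) scale, which understates changes of low values. The contrasts were LC minus LP, each hybrid minus each parent, each hybrid and the mean of both minus the mid-parent (the mean of LP and LC on the log2 scale), and LPC minus LCP. The mid-parent on the log2 scale lies below the mean of the parents' FPKM when the parents differ, so an ID found in 1 parent only is called above it even when the hybrids carry the parents' average FPKM. Counts against log2 of the linear mean, with a delta-method error, were computed as an alternative.

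Inheritance classes used the calls of LC minus LP and of a hybrid against each parent. An LP-like ID was told apart from LC and not from LP, which does not show equality with LP. The position of a hybrid library is the median, over IDs called between LC and LP, of its place between the parental means, with -1 at the LP mean and 1 at the LC mean. Positions of LPC and LCP were compared by exact permutation of 3 against 3 libraries, for which the smallest 2-sided p is 0.1. The share of the FPKM sum taken by the 10 most abundant IDs, and the number of IDs at an FPKM of at least 1, were compared between the 6 hybrid and 6 parental libraries of a tissue by exact 2-sided permutation, where the smallest p is 0.00216. Differences of these measures between tissues were tested by permuting hybrid and parental libraries within each tissue, over all assignments, and again with same-numbered libraries of a cross moved together. A difference between tissues in the hybrid departure was tested by limma on all 36 libraries over IDs that passed the filter in both tissues.

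Before the data were examined, the groups, tests, alternatives and 44 lists of gene symbols were fixed, together with a rule for named genes. The rule took the 5 highest and 5 lowest fold changes per tissue and contrast among called genes with a symbol, a mean FPKM of at least 5 in at least 1 cross and no overlap between the libraries of both sides. For the mid-parent this meant all 6 hybrid libraries on 1 side of the log2 mid-parent mean, so hybrid libraries can overlap those of 1 parent. With no symbols in the table, 0 list members could be matched. The list tests, the marker lists for other cell types, the markers for tissue labels and the growth axis genes were therefore not run. The rule was applied without its symbol criterion, and at most 2 IDs each way are printed per tissue and contrast. To these was added, in liver and muscle, the first of the 3 most abundant IDs called against the mid-parent. This change to the rule was made after the values were seen, and so was the following grouping. An ID is tissue-enriched when its mean log2 value over the 4 crosses, each with equal weight, was at least 4-fold above that of both other tissues. It is broad when its 3 tissue means lay within 2-fold of each other and its lowest was at least 1 on the log2 scale. These 4 groups were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the groups of a tissue and contrast.

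The fixed alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, a shift of log2 values to a common median, the replicate number as a term, a linear mid-parent, a threshold on the parental difference for the position, and leaving out each library in turn. After the data were seen, 4 further ones were added. The first, median-ratio scaling, divides each library's FPKM by the median ratio to the tissue mean over IDs at an FPKM of at least 1 in all 12 libraries (12898 in brain, 7544 in liver and 5508 in muscle). The others were the first residual component as a covariate in brain, libraries of the same number paired across tissues, and the share of the 1 or 100 most abundant IDs. Scaling by a median assumes that most IDs do not differ, which these data cannot check.

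The fits were tested on simulated data drawn from the real means and spreads, with 100 IDs changed by each of 2 sizes. At a log2 change of 1, the share recovered for LC against LP was 9% of the changed IDs in brain, 22% in liver and 34% in muscle. At a log2 change of 2 it was 73%, 86% and 88%. For the hybrids against the mid-parent it was 42%, 64% and 79% at a change of 1, and 80%, 91% and 99% at a change of 2. Between 1 and 8 unchanged IDs were called. Results of fits across IDs were also counted under other assignments of the same libraries to the crosses, all 10 splits for 3 against 3 libraries and 100 otherwise, drawn without regard to replicate numbers, with the real one included. For differences between tissues, assignments that move same-numbered libraries together were drawn as well. Figures were drawn with matplotlib 3.10.9.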

Results

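Expression was measured by RNA sequencing in brain, liver and muscle of small yellow croaker (LP), large yellow croaker (LC) and both reciprocal hybrids (LPC and LCP), with 3 libraries in each of the 12 groups. The series concerns growth-related heterosis, the departure of hybrids from their parents, and the comparisons follow from that: how far the parental species differed, where the hybrids lay relative to them, and whether the 2 hybrids differed. Values are FPKM and the depth of each library is unknown. IDs listed at an FPKM of at least 1 numbered 15122 to 17177 per library in brain, 9437 to 11839 in liver and 7179 to 10645 in muscle. Across all libraries, the first 2 principal components held 57.2% and 26.6% of the variance. Brain libraries lay between -227.8 and -194.1 on the first, against 91.0 to 130.2 for liver and 83.9 to 134.1 for muscle. The second set liver libraries (-132.3 to -113.6) apart from muscle libraries (111.3 to 138.9). No library lay among those of another tissue. Within groups, the median Spearman correlation across IDs was 0.86 in brain, 0.89 in liver and 0.891 in muscle. Between LP and LC it was 0.848, 0.741 and 0.746.

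A few IDs took much of the signal in liver and muscle, and their share differed between hybrids and parents in opposite ways. In liver, the 10 most abundant IDs of a library held 48.1% ± 4.19 (SD, n = 6) of the FPKM sum in hybrids and 36.4% ± 6.72 (SD, n = 6) in parents (exact permutation p = 0.00649, adjusted p = 0.0195). In muscle they held 35.4% ± 4.48 (SD, n = 6) in hybrids and 47.7% ± 5.26 (SD, n = 6) in parents (exact permutation p = 0.00433, adjusted p = 0.0195). In brain they held 6.74% ± 1.95 (SD, n = 6) and 5.35% ± 0.616 (SD, n = 6), a difference within the spread (exact permutation p = 0.162, adjusted p = 0.244). Hybrid livers also listed fewer IDs at an FPKM of at least 1, 10246 ± 735 (SD, n = 6) against 11380 ± 347 (SD, n = 6) in parents (exact permutation p = 0.013, adjusted p = 0.026). Most of this was in LCP, with 9651 ± 198 (SD, n = 3), while LPC had 10840 ± 501 (SD, n = 3) and overlapped the parents, at 11450 ± 253 in LP and 11310 ± 471 in LC (SD, n = 3 each). These numbers did not differ beyond the spread in brain, at 16368 ± 712 in hybrids and 15960 ± 771 in parents (SD, n = 6 each; exact permutation p = 0.37, adjusted p = 0.37), or in muscle, at 9404.5 ± 792 and 8723 ± 1444 (SD, n = 6 each; exact permutation p = 0.323, adjusted p = 0.37). In muscle the parents did not overlap, at 9961 ± 593 in LP and 7485 ± 513 in LC (SD, n = 3 each). LPC muscle had 10038 ± 252 and LCP muscle 8771 ± 549 (SD, n = 3 each). The adjustment covers 6 comparisons. In liver the direction held for the 100 most abundant IDs and not for the single most abundant ID of a library. Crosses of 1 kind differed too. LP liver held 41.4% ± 5.68 (SD, n = 3) in these 10 IDs and LC liver 31.3% ± 2.07 (SD, n = 3), against 45.5% ± 3.63 in LPC and 50.7% ± 3.15 in LCP (SD, n = 3 each), and 1 LP liver library, at 48.0%, lay within the range of the hybrids. LC muscle held 51.4% ± 4.86 (SD, n = 3) and LP muscle 44.0% ± 2.05 (SD, n = 3). LPC muscle held 32.3% ± 1.6 and LCP muscle 38.5% ± 4.4 (SD, n = 3 each). In muscle 1 LCP library, at 43.5%, lay within the range of LP (41.7% to 45.5%). LP against LC, and LPC against LCP, each gave an exact permutation p of 0.1 in liver and in muscle, the smallest that 3 libraries against 3 allow. The tests of 6 against 6 libraries pool 2 crosses per side. They speak against all crosses being alike and do not test hybrids against parents by themselves.

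**Figure D1:**
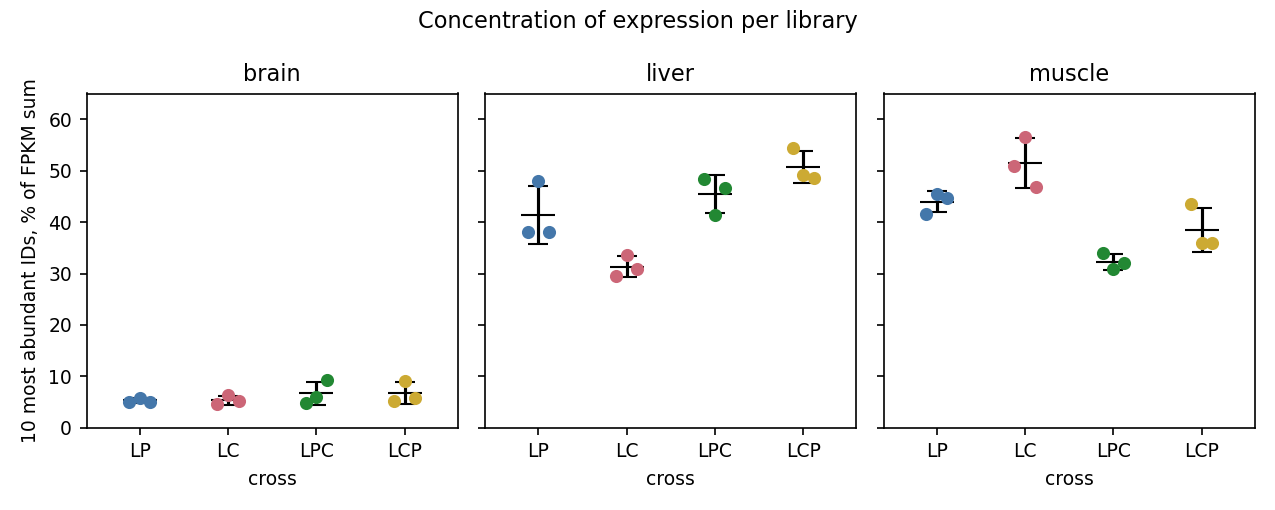
Share of the FPKM sum (%) held by the 10 most abundant IDs of each library, by cross (x axis) and tissue (panels); points are libraries, dashes are means and bars are SDs of 3 libraries. Hybrid liver libraries lay between 41.4% and 54.3%, and hybrid muscle libraries between 30.9% and 43.5%.

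Between LP and LC, the most IDs were called in muscle, fewer in liver and the fewest in brain. In muscle, 331 IDs were higher and 5260 lower in LC than in LP, with a median log2 difference over all IDs tested of -0.64. After median-ratio scaling, which brought that median to -0.09, 1068 were higher and 1440 lower, and 327 and 1440 were called the same way under both scalings. Quantile normalization gave 1220 higher and 1251 lower, and a shift of the log2 values to a common median gave 1923 higher and 817 lower (median 0.20), so which side held more calls depended on the scaling. In liver, 1013 IDs were higher and 944 lower in LC, with a median of 0.01, and 838 and 890 were called the same way under both. In brain, 301 were higher and 312 lower, against 390 and 238 after scaling and 396 and 231 after the shift to a common median, although more IDs were tested in brain than in muscle. In simulated data a log2 change of 1 was recovered for 9% of changed IDs in brain, 22% in liver and 34% in muscle. The counts therefore cannot by themselves order the tissues by how far the species differed. By median Spearman correlation, LP and LC lay close to the within-group value in brain (0.848 against 0.86). They lay further below it in liver (0.741 against 0.89) and muscle (0.746 against 0.891). Of the 613 called in brain, fewer were left without LP 1 (262), LP 3 (276), LC 1 (358), LC 2 (310) or LC 3 (277). The calls used limma's test with Benjamini-Hochberg adjustment.

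Several parental differences were close to presence against absence. In muscle, BGI_novel_G002583 had an FPKM of 19800 ± 6967 (SD, n = 3) in LC and was listed at 0 in all LP libraries (limma adjusted p = 6.30e-07), while BGI_novel_G000025 had 3636 ± 1183 (SD, n = 3) in LP and was listed at 0 in LC (limma adjusted p = 5.55e-11). Both were present in both hybrids, BGI_novel_G002583 at 5871 ± 3753 in LPC and 4752 ± 6031 in LCP, and BGI_novel_G000025 at 2358 ± 310 and 2017 ± 279 (SD, n = 3 each). In liver, evm.model.Chr16.191 had 3122 ± 2489 in LP and 4.40 ± 7.44 in LC (SD, n = 3 each; log2 change -9.85, SE 0.97, limma adjusted p = 1.06e-04). In the hybrids it had 514 ± 262 in LPC and 16.8 ± 6.99 in LCP (SD, n = 3 each). BGI_novel_G002270 had 959 ± 325 in LP liver against 0.10 ± 0.11 in LC liver (SD, n = 3 each; limma adjusted p = 2.21e-08), and 1858 ± 633 and 1396 ± 374 in LPC and LCP. BGI_novel_G001511 ran the other way in liver, with 488 ± 150 in LC and 0.08 ± 0.14 in LP (SD, n = 3 each; limma adjusted p = 2.56e-07). It was also higher in LC brain, at 347 ± 120 against 0.09 ± 0.16 in LP (SD, n = 3 each; limma adjusted p = 2.14e-04). In brain, evm.model.Chr15.765 had 545 ± 177 in LC and 1.09 ± 0.17 in LP (SD, n = 3 each; log2 change 7.97, SE 1.12, limma adjusted p = 3.45e-03). Its hybrid levels were 57.8 ± 92.3 in LPC and 24.2 ± 4.49 in LCP, closer to LP than to LC in FPKM.

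Tissue-enriched IDs were called in both directions between the parental species. Of the 554 muscle-enriched IDs, 63 were higher and 183 lower in LC muscle, with 308 not called. Relative to the other IDs tested their median log2 difference was higher by 0.215, and by 0.51 after scaling, when 129 were higher and 64 lower. The camera test gave an adjusted p of 1.35e-06 with the preset correlation, and adjusted p = 0.178 with an estimated correlation, at which the call was lost. With quantile normalization the median was higher by 0.245 and the call was lost at the preset correlation as well (camera adjusted p = 0.276). Of the 806 liver-enriched IDs, 94 were higher and 112 lower in LC liver, with a median 0.02 above that of the other IDs while the camera test pointed lower (camera adjusted p = 0.729, and adjusted p = 0.882 with an estimated correlation).

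Against the mid-parent, as deposited, calls in the hybrids were mostly lower in liver and mostly higher in muscle, and both balances turned round under other scalings. In liver, 331 IDs were higher and 3749 lower in the mean of the hybrids, with a median of -0.35 over all IDs. After scaling, with the median at -0.045, 515 were higher and 423 lower, and 313 and 423 were called the same way under both. Quantile normalization gave 537 higher and 426 lower in liver, and the shift to a common median 625 and 307. In muscle, 4640 were higher and 479 lower, with a median of 0.38. After scaling (median -0.05), 1708 were higher and 2215 lower, and 1708 and 479 were called the same way under both. Quantile normalization gave 1644 higher and 1800 lower in muscle, and the shift to a common median 1308 and 4391 (median -0.30). IDs with at least a 2-fold difference as deposited and after median-ratio scaling numbered 185 higher and 161 lower in liver, and 576 higher and 106 lower in muscle. Such joint counts keep only what passes on both scales, so their balance also carries the shift between these scales. In muscle, all 479 IDs called lower as deposited and all 1708 called higher after scaling were called under both. The excess of higher IDs in the joint muscle counts therefore shows no direction that holds under both scalings. In brain, limma called 7 higher and 2 lower, against 6 and 2 after scaling and 8 and 6 with quantile normalization. Against the linear mid-parent, 1 was higher and 9 lower in brain. The 9 brain calls became 5 without LP 1 or LC 1, 2 without LC 2, and 4 without LCP 2 or LCP 3.

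**Figure D2:**
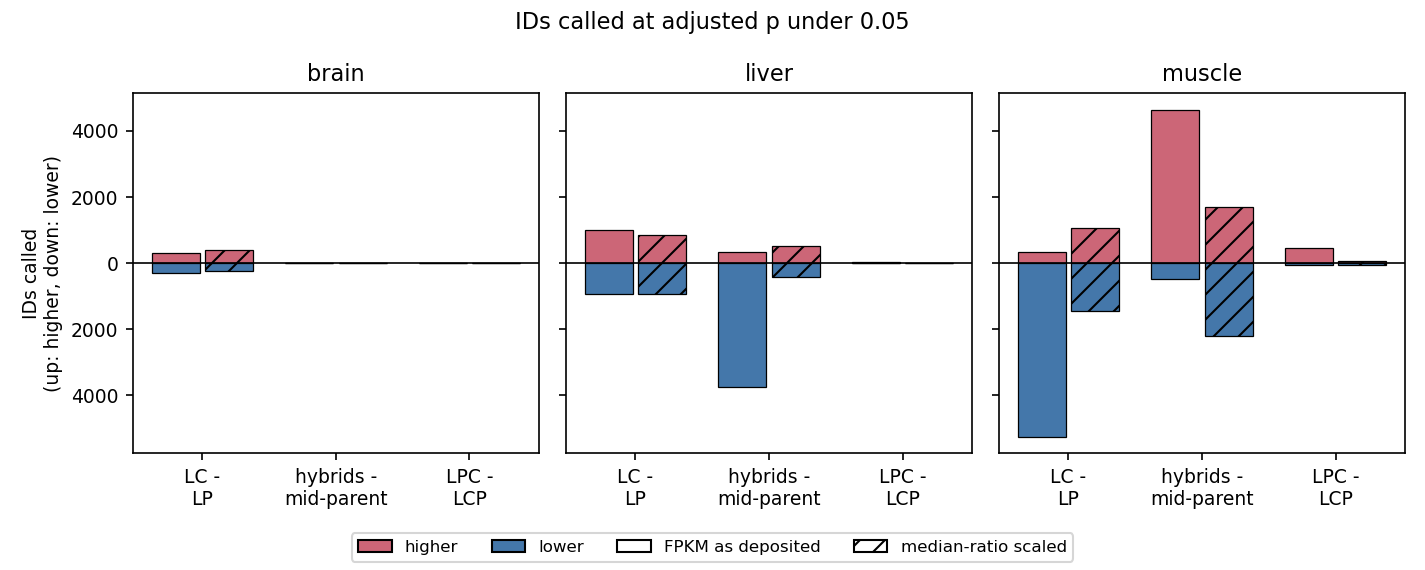
Number of IDs called higher (up) or lower (down) for LC against LP, the mean of the hybrids against the mid-parent, and LPC against LCP, per tissue. Plain bars are from FPKM as deposited and hatched bars from median-ratio scaled FPKM. In muscle the hybrid calls were 4640 higher and 479 lower as deposited and 1708 and 2215 after scaling, and a shift to a common median, not drawn, gave 1308 and 4391.

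Among the IDs called against the log2 mid-parent, some lay outside the libraries of both parents and others within those of 1 parent. The abundant liver ID evm.model.Chr16.833 had 89900 ± 29260 in LPC and 97810 ± 6209 in LCP against 41430 ± 6158 in LP and 26320 ± 460 in LC (SD, n = 3 each), 2.80-fold above the mid-parent (log2 change 1.49, SE 0.14, limma adjusted p = 2.88e-04). BGI_novel_G000372 had 1549 ± 1094 in LPC liver and 1745 ± 588 in LCP liver against 510 ± 370 in LP, and was listed at 0 in LC (limma adjusted p = 1.16e-04). Its LPC and LP libraries overlapped, and the log2 mid-parent it was called against lies low because of LC. In the opposite direction, evm.model.Chr15.515 had 1.71 ± 1.68 in LPC and 1.73 ± 1.32 in LCP against 101 ± 27.6 in LP and 193 ± 168 in LC (SD, n = 3 each), 40.9-fold below the mid-parent (log2 change -5.36, SE 0.71, limma adjusted p = 1.68e-03). evm.model.Chr11.367 had 333 ± 47.0 in LC liver and 14.1 ± 12.7 in LP liver, 0.26 ± 0.45 in LCP, and was listed at 0 in LPC (SD, n = 3 each; limma adjusted p = 1.11e-05).

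In muscle, BGI_novel_G002609 was near absent from both parents, at 0.32 ± 0.56 in LP and listed at 0 in LC, and reached 443 ± 306 in LPC and 378 ± 28.7 in LCP (SD, n = 3 each; limma adjusted p = 5.87e-07). The most abundant muscle ID, evm.model.Chr1.830, was lower in hybrids, at 51220 ± 5742 in LPC and 66490 ± 11120 in LCP against 86550 ± 15410 in LP and 130000 ± 19360 in LC (SD, n = 3 each), 1.81-fold below the mid-parent (log2 change -0.86, SE 0.13, limma adjusted p = 3.57e-04). Its LCP and LP libraries overlapped. Quantile normalization gives the top-ranked ID 1 value in all libraries, and its difference is then 0. evm.model.Chr14.707 had 5287 ± 4306 in LC muscle and 61.8 ± 56.2 in LP muscle, against 16.7 ± 3.49 in LPC and 46.1 ± 43.0 in LCP (SD, n = 3 each; log2 change -4.08, SE 0.59, limma adjusted p = 3.37e-04), so that the hybrid libraries overlapped those of LP. BGI_novel_G002574 had 4697 ± 4311 in LP and was listed at 0 in LC, and its levels in LPC and LCP were 4482 ± 2593 and 3622 ± 1669 (SD, n = 3 each; limma adjusted p = 6.11e-05 against the log2 mid-parent), within the spread of LP. In brain, evm.model.Chr23.828 was called above the log2 mid-parent (limma adjusted p = 9.71e-06) with 64.9 ± 4.47 in LPC and 68.2 ± 14.2 in LCP (SD, n = 3 each). Its parental FPKM averaged 57.3 on the linear scale, from 115 ± 7.07 in LC and 0.06 ± 0.10 in LP.

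In hybrid muscle, broadly expressed IDs had a higher median than the other IDs tested, and brain-enriched and liver-enriched IDs a lower one. The hybrid shift in muscle was larger in abundant IDs, with a median of 0.888 at a mean FPKM of at least 20 against 0.382 over all. The log2(FPKM + 1) scale understates changes of low values, which makes part of this gap. The groups were not matched for abundance, so its part in their medians was not tested. Of the 884 broad IDs, 526 were higher, 24 lower and 334 not called in muscle, and their median was 0.38 above that of the other IDs (0.27 above after scaling, with 237 higher and 147 lower). The camera adjusted p was 0.00358 with the preset correlation, and adjusted p = 0.5 with an estimated correlation; after scaling these were 0.0019 and 0.032. The 2104 brain-enriched IDs tested in muscle had a median of -0.24 relative to the others (595 higher, 80 lower), and of -0.21 after scaling (131 higher, 606 lower), with camera adjusted p = 0.00361 preset and adjusted p = 0.5 with an estimated correlation. The 201 liver-enriched IDs tested in muscle had a median of -0.29 relative to the others (53 higher, 16 lower; camera adjusted p = 7.96e-04 preset, adjusted p = 0.5 with an estimated correlation). After scaling it was -0.23, with 21 higher and 51 lower, and the preset call was lost (camera adjusted p = 0.0507). In hybrid brain, broad IDs had a median of 0.13 and brain-enriched IDs of -0.155 relative to the others (camera adjusted p = 8.50e-06 preset for each, adjusted p = 0.383 with an estimated correlation for each), with 0 of 884 and 3 of 5196 called. In hybrid liver, 103 of the 806 liver-enriched IDs were higher and 202 lower, against 132 and 41 after scaling. Their median lay 0.06 above that of the other IDs as deposited and 0.16 above after scaling (camera adjusted p = 3.50e-06 preset, adjusted p = 0.153 with an estimated correlation). The 2229 brain-enriched IDs tested in liver had a median of -0.07 relative to the others, with 22 higher and 874 lower (camera adjusted p = 0.00135 preset, adjusted p = 0.381 with an estimated correlation). After scaling 33 were higher and 84 lower, and with quantile normalization 38 and 77, with medians of -0.096 and -0.085.

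The hybrid departure differed between tissues for many IDs in the test of the difference itself. Between muscle and liver, 5419 IDs had a higher departure in muscle and 72 a lower one, against 866 and 448 after scaling and 574 and 481 with quantile normalization. Between muscle and brain the counts were 3290 and 250, against 863 and 998 after scaling and 923 and 762 with quantile normalization. Between liver and brain they were 115 and 1678, against 181 and 249 after scaling and 284 and 230 with quantile normalization. With same-numbered libraries of a cross paired across tissues, the 1793 calls between liver and brain became 908 (68 higher, 840 lower).

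Both hybrids departed from the mid-parent in part in the same IDs. In liver, 206 IDs were higher in LPC and 224 in LCP, and 92 were in both lists, where independent lists of these sizes would share 3.7. For lower IDs the lists held 490 and 4874, with 444 in both and 190.3 from independent lists. The LPC liver counts depended on single libraries: 121 higher and 209 lower without LP 3, 114 and 184 without LC 1, 319 and 904 without LC 2, 128 and 140 without LPC 1, 59 and 48 without LPC 2, which turned the balance, and 75 and 101 without LPC 3. The 5098 calls for LCP liver became 2251, 3135 and 3108 without LCP 1, LCP 2 and LCP 3, and the 2974 for LCP muscle 1339 without LCP 3. In muscle, 5051 and 2411 were higher, with 2117 in both (1122.7 from independent lists), and 258 and 563 lower, with 135 in both (13.4 from independent lists). After scaling, LPC liver had 240 higher and 147 lower IDs and LCP liver 307 and 192, with 122 higher and 57 lower in both lists (5.9 and 2.2 from independent lists). LPC muscle then had 1378 higher and 1363 lower and LCP muscle 1152 and 1769, with 636 and 842 in both (146.3 and 222.3 from independent lists). With quantile normalization the higher and lower IDs numbered 251 and 158 for LPC and 280 and 186 for LCP in liver, and 1298 and 1409 for LPC and 970 and 1098 for LCP in muscle. With the shift to a common median they numbered 268 and 149, 379 and 109, 1137 and 3719, and 1003 and 3534 in the same order. The 2 departures share the parental libraries, so part of the overlap may come from these. An ID found in 1 parent only also lies above the log2 mid-parent when both hybrids carry the parents' average FPKM. The simulated groups below hold no such IDs, so part of the excess over them may come from this. Against the linear mid-parent, higher and lower IDs in liver numbered 158 and 667 for LPC, and 162 and 5328 for LCP. Across IDs the departures had a correlation of 0.694 in liver and 0.697 in muscle, against 0.312 and 0.306 in simulated unchanged groups, and covariances of 0.268 and 0.387 against 0.0324 and 0.0287. In brain the correlation was 0.398 against 0.329 simulated, and the covariance 0.0899 against 0.0578. IDs are not independent replicates. With 3 libraries per parent, the parents could not be divided between the hybrids with 2 libraries each.

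Relative to both parents, LCP in liver and LPC in muscle had the more IDs outside the parental range as deposited, and in muscle this order turned round after median-ratio scaling but not with quantile normalization. In liver, LCP had 64 IDs above and 1785 below both parents, against 59 and 89 for LPC. After scaling these became 106 and 37 for LCP and 76 and 23 for LPC. In muscle, LPC had 1324 IDs above and 47 below both parents, against 486 and 117 for LCP, and after scaling 387 and 313 for LPC and 330 and 566 for LCP. With quantile normalization muscle had 379 and 361 for LPC and 243 and 313 for LCP. LP-like IDs outnumbered LC-like IDs in muscle, 3892 against 296 for LPC and 3044 against 856 for LCP (1415 against 336 and 1234 against 509 after scaling). In liver the numbers were 622 and 373 for LPC and 794 and 741 for LCP (476 and 275, and 388 and 412 after scaling). In brain, LC-like IDs were the more frequent, 82 against 31 for LPC and 85 against 26 for LCP, and 3 and 0 IDs lay outside both parents. Without LP 3, LPC brain had 29 LC-like and 29 LP-like IDs, so this excess rested on that library for LPC. The LC-like number in LPC brain was also lower without LP 1 (49), LPC 1 (44) or LPC 2 (37), and the LP-like number without LC 1 (18) or LPC 3 (20). For LCP brain the LC-like number became 46, 44, 53, 52, 46 and 42 without LP 1, LP 3, LC 3, LCP 1, LCP 2 and LCP 3, above the LP-like number each time. In liver, LC-like IDs outnumbered LP-like IDs for LPC without LC 1 (373 against 338), and for LCP without LP 2 (541 against 514) or LC 1 (663 against 488). LPC liver had 360 LP-like IDs without LPC 2, and 155, 197 and 178 LC-like IDs without LP 3, LPC 2 and LPC 3, and LCP liver 426 LC-like IDs without LP 3. In muscle the LC-like number fell to 184, 132 and 118 for LPC without LP 2, LPC 2 and LPC 3, and to 328 and 491 for LCP without LP 2 and LCP 1. The 148 IDs of LPC liver outside both parents became 61 without LP 3, 80 without LC 1, 286 without LC 2, 53 without LPC 2 and 61 without LPC 3. The 1849 of LCP liver became 1030 without LP 3, 990 without LC 1, and 668, 1007 and 991 without LCP 1, LCP 2 and LCP 3. The 1371 of LPC muscle became 561 without LP 3, 400 without LPC 2 and 398 without LPC 3, and the 603 of LCP muscle 291 without LP 2, 345 without LP 3 and 249 without LCP 3.

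Over the IDs that separated the species, muscle of both hybrids lay towards LP. Mean positions in muscle were -1.21 ± 0.21 (SD, n = 3) for LPC and -0.54 ± 0.42 (SD, n = 3) for LCP, and -0.63 ± 0.02 and -0.42 ± 0.32 after scaling. In liver they were -0.17 ± 0.02 and -0.09 ± 0.02 (SD, n = 3), with LCP at 0.02 ± 0.06 after scaling, and LCP liver also changed sides without LP 2 (0.11) or LC 1 (0.03). LPC liver was at -0.05 without LP 1 or LP 2, -0.07 without LC 1, -0.28 without LC 2 and -0.32 without LC 3, and LCP liver at -0.04, -0.31 and -0.35 without LP 1, LC 2 and LC 3. In brain they were 0.13 ± 0.06 and 0.17 ± 0.08 (SD, n = 3), with LPC brain at 0.34 without LP 2, 0.07 without LC 2, 0.06 without LC 3 and 0.05 without LPC 1. LCP muscle was at -0.32 without LCP 3. The hybrids could not be separated at 0.05 by exact permutation of 3 against 3 libraries. As deposited, exact permutation gave p = 0.1 in liver and muscle, the smallest value possible, and p = 0.6 in brain. In muscle, exact permutation gave p = 0.4 after median-ratio scaling, when LCP 1 (-0.656) lay closer to LP than every LPC library. Exact permutation gave p = 0.2 in muscle with quantile normalization, a pseudocount of 0.1 or the threshold on the parental difference. In liver, exact permutation gave p = 0.1 in each of these settings.

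**Figure D3:**
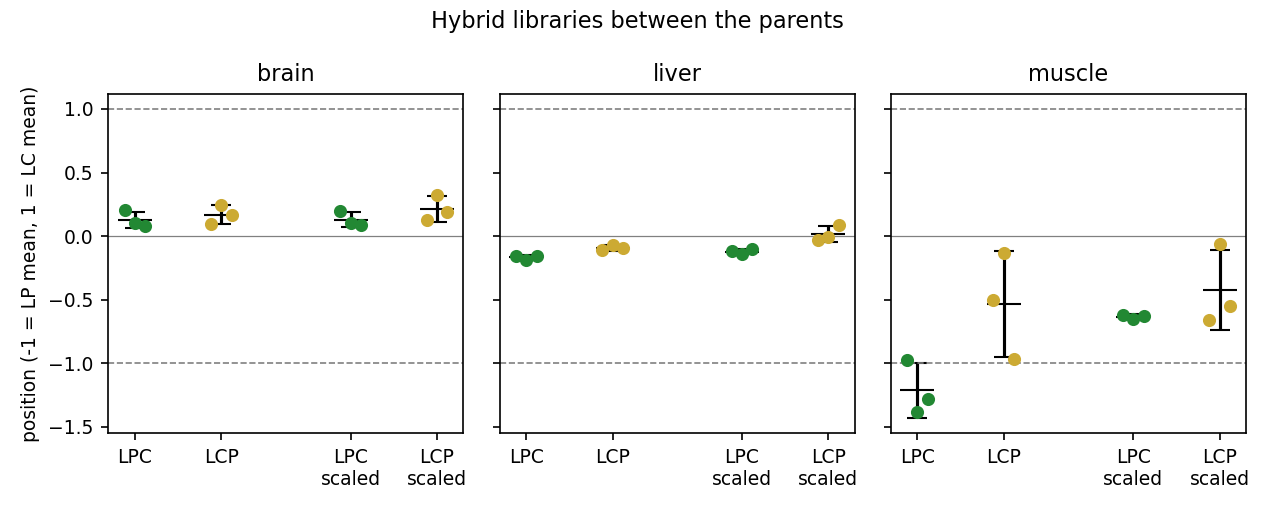
Position of each hybrid library between the parents (y axis, median over IDs called between LC and LP; -1 is the LP mean and 1 the LC mean, dashed), as deposited and after median-ratio scaling, per tissue. Points are libraries, dashes are means and bars are SDs of 3 libraries. In muscle, LPC libraries averaged -1.21 as deposited and -0.63 after scaling.

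Few IDs were called between the 2 hybrids, which does not show that few differed. IDs at an unadjusted limma p under 0.05 numbered 3110 of 10847 in muscle and 2552 of 12553 in liver (1873 and 942 after scaling), and 642 of 17931 in brain. With no difference a share of 0.05 is expected. Muscle and liver lay above it, also after scaling, and brain below it. The brain number became 1198 without LCP 3, 1021 without LPC 1 and 393 without LCP 1, and 1058 with the replicate number as a block. In muscle, 473 were higher and 45 lower in LPC than in LCP, and 66 and 45 after scaling, of which 66 and 31 were called under both. Quantile normalization gave 40 and 37 in muscle, and the shift to a common median 108 and 111. The 518 calls in muscle became 66 without LPC 2, 54 without LPC 3, 189 without LCP 1, 132 without LCP 2 and 1184 without LCP 3. In liver, 24 were higher and 6 lower, against 9 and 10 after scaling, 12 and 14 with quantile normalization and 6 and 10 after the shift to a common median. The 30 calls in liver became 16, 10 and 18 without LPC 1, LPC 2 and LPC 3, and 12, 13 and 13 without LCP 1, LCP 2 and LCP 3. In brain limma called 0 (0 after scaling, 5 with quantile normalization). BGI_novel_G002127 followed LC and LCP in every tissue. In muscle it had 279 ± 177 in LC and 135 ± 9.76 in LCP (SD, n = 3 each) and was listed at 0 in LP and LPC (limma adjusted p = 1.11e-05 between the hybrids). In liver it had 38.5 ± 29.1 in LC and 13.9 ± 1.34 in LCP (SD, n = 3 each), again at 0 in the other crosses (limma adjusted p = 1.15e-02). BGI_novel_G002561 ran the other way in muscle, with 4617 ± 4546 in LC and 1831 ± 1334 in LPC against 0.05 ± 0.09 in LP and 1.97 ± 1.05 in LCP (SD, n = 3 each; limma adjusted p = 7.23e-04 between the hybrids). In liver, evm.model.Chr21.1156 had 12.2 ± 4.59 in LPC (SD, n = 3) and was listed at 0 in LCP (limma adjusted p = 2.15e-02), a call that was lost when any of 5 of the 6 hybrid libraries was left out. Muscle-enriched IDs had a median log2 difference of -0.37 relative to the other IDs in LPC against LCP muscle, with 6 higher and 6 lower of 554 (camera adjusted p = 1.82e-14 preset, adjusted p = 0.0255 with an estimated correlation). With an estimated correlation the call was lost after scaling (median -0.45, adjusted p = 0.0743) and with quantile normalization (median -0.23, adjusted p = 0.238).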

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

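The tests on the 10 and the 100 most abundant IDs were chosen after the result was seen, as were median-ratio scaling, the assignments that keep same-numbered libraries together and the IDs named below. Departures of the hybrids from the mid-parent differed between tissues in the test of the difference itself. The limma test called 1793 IDs between liver and brain, 3540 between muscle and brain and 5491 between muscle and liver. Of 100 assignments drawn in each tissue separately, the labelled one included, 1 gave as many in each comparison, and the highest other counts were 1475, 2964 and 1754. These do not keep same-numbered libraries of different tissues together, which deviated together. With such libraries moved together, 1 of 100 gave as many in each comparison, and the highest other counts were 825, 2039 and 4238. In fits of the differences between same-numbered libraries the calls numbered 908 between liver and brain, 3464 between muscle and brain and 6028 between muscle and liver. The highest other counts were 312, 1358 and 4463, again with 1 of 100 each. All these assignments were drawn on FPKM as deposited and mix parents and hybrids. The difference between the species then enters the spread of the others. They speak against all crosses being alike and do not test the difference in departure by itself.

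Differences between tissues in single IDs are given on the log2 scale with limma adjusted p-values. The fit of all 36 libraries had no term for same-numbered libraries, which deviated together across tissues. These p-values take no account of that, and none with such pairs are given for single IDs. Against the mid-parent, evm.model.Chr11.367 departed by -5.83 in liver and -0.11 in brain, a difference of -5.72 (adjusted p = 6.77e-11), and by -0.03 in muscle, 5.80 above liver (adjusted p = 3.49e-11). evm.model.Chr23.828 departed by 0.74 in liver and 2.60 in brain, a difference of -1.86 (adjusted p = 1.91e-03). BGI_novel_G001303 departed by 0.03 in muscle and 2.25 in brain, a difference of -2.22 (adjusted p = 1.76e-05). BGI_novel_G000372 departed by 1.73 in muscle and 6.197 in liver, a difference of -4.47 (adjusted p = 3.70e-07). In brain, evm.model.Chr23.828 and BGI_novel_G001303 were near 0 in 1 parent, as was BGI_novel_G000372 in liver. The log2 mid-parent then lies low and makes part of these departures. In FPKM, hybrids and linear mid-parent were at 66.5 and 57.3, 24.85 and 10.78, and 1647 and 254.9 in the same order. evm.model.Chr14.707 departed by -4.08 in muscle and 1.14 in liver, a difference of -5.22 (adjusted p = 1.31e-06), and evm.model.Chr16.833 by -0.41 and 1.49, a difference of -1.90 (adjusted p = 1.89e-02).

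Between LC and LP, the difference of BGI_novel_G002270 was -9.72 in liver and -5.47 in brain, apart by -4.25 (adjusted p = 3.63e-02). That of BGI_novel_G000025 was -11.78 in muscle and -0.54 in brain, apart by -11.24 (adjusted p = 5.22e-14). That of BGI_novel_G002556 was 11.77 in muscle and -0.03 in brain, apart by 11.80 (adjusted p = 5.18e-06), and that of BGI_novel_G002583 was 14.22 and 2.27, apart by 11.94 (adjusted p = 2.19e-07). These fitted values involve groups listed at or near 0 and are no measure of fold.

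The share of the 10 most abundant IDs, hybrids minus parents, was higher by 10.3 percentage points in liver than in brain (exact permutation, adjusted p = 0.033). It differed by -13.7 between muscle and brain (exact permutation, adjusted p = 0.002) and by -24.0 between muscle and liver (exact permutation, adjusted p = 0.000211). The number of IDs at an FPKM of at least 1, hybrids minus parents, differed by -1543 between liver and brain (exact permutation, adjusted p = 0.0251) and by 1816 between muscle and liver (exact permutation, adjusted p = 0.033). It did not differ detectably between muscle and brain (273, exact permutation, adjusted p = 0.738, and 0.667 with same-numbered libraries moved together). These tests permute each tissue separately, with the 2 crosses of each side pooled. With same-numbered libraries of a cross moved together, the adjusted p by exact permutation was 0.0156, 0.013 and 0.013 for the shares in the same order and 0.0156 for the other 2 differences in the number of IDs, and 0.00216 before adjustment is the smallest p these permutations can give.

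As deposited, calls against the mid-parent were mostly lower in liver and higher in muscle, and calls of LC against LP in muscle mostly lower, with median log2 differences of -0.35, 0.38 and -0.64. Dividing by the FPKM sum without the 10 most abundant IDs left -0.113 in liver, and 0.299 and -0.561 in muscle. The values left in muscle argue against these 10 as the whole cause there. Without the 100 most abundant, -0.108 was left in liver and 0.057 in hybrid muscle. For LC against LP in muscle -0.398 was left, which argues against the 100 as the whole cause there. This division removes any shift common to the remaining IDs, whatever its cause. The small values left in liver and hybrid muscle therefore cannot tell abundant IDs from a change in most genes. A difference in depth would act mainly on low values, yet the medians over IDs with a mean FPKM of at least 20 were -0.376, 0.888 and -0.81, which argues against it. The log2(FPKM + 1) scale understates changes of low values. Only the presence of a shift in abundant IDs therefore bears on depth, and not its larger size. A difference between the crosses in the amount of RNA from most genes stays open and was not tested.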

How the results depend on the processing

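Median-ratio scaling, the brain component, the pairing across tissues and the number of most abundant IDs were chosen after the data were seen. Values are numbers of IDs called unless a position, share or median is named, each with the value as reported in brackets, and causes were not tested except where stated. Scalings that centre the libraries of a tissue lowered most of the counts they moved in liver and muscle. Depth is unknown and sets no stated limit. With the single most abundant ID in place of 10, liver top-10 share, hybrids against parents was -0.39 (11.7). With the first residual component of brain as a covariate, brain LC against LP was 1550 (613), brain LPC against LP was 1099 (97), brain LPC against LC was 123 (41), brain LCP against LP was 152 (91), brain LPC against LCP was 4 (0), brain LPC against mid-parent was 239 (7), brain LCP against mid-parent was 13 (2), brain hybrids against mid-parent was 58 (9). With the replicate number as a block, brain LPC against LP was 157 (97), brain LPC against mid-parent was 1 (7), brain LCP against mid-parent was 1 (2), liver LPC against LCP was 16 (30), liver LPC against mid-parent was 416 (696). With a pseudocount of 0.1, brain LPC against LCP was 5 (0), brain LPC against mid-parent was 18 (7), brain LCP against mid-parent was 18 (2), brain hybrids against mid-parent was 32 (9), muscle LPC against LCP was 202 (518), brain LPC outside both parents was 1 (3), brain LCP outside both parents was 1 (0), liver LCP position was -0.069 (-0.092), liver LPC against LCP, liver-enriched median against the rest was -0.099 (0.008). With no filter on low values, brain LPC against LCP was 1 (0), brain LCP against mid-parent was 6 (2), liver LPC against mid-parent was 349 (696), muscle LPC against LCP was 226 (518), brain LPC outside both parents was 5 (3), brain LCP outside both parents was 1 (0). With quantile normalization, brain LPC against LCP was 5 (0), brain LPC against mid-parent was 3 (7), brain hybrids against mid-parent was 14 (9), liver LCP against LP was 800 (4193), liver LCP against LC was 771 (4152), liver LPC against mid-parent was 409 (696), liver LCP against mid-parent was 466 (5098), liver hybrids against mid-parent was 963 (4080), muscle LC against LP was 2471 (5591), muscle LPC against LC was 3524 (6883), muscle LCP against LC was 2887 (4625), muscle LPC against LCP was 77 (518), muscle LPC against mid-parent was 2707 (5309), brain LCP outside both parents was 2 (0), liver LCP outside both parents was 128 (1849), muscle LPC outside both parents was 740 (1371), liver LPC position was -0.13 (-0.17), liver LCP position was 0.010 (-0.092), muscle LPC position was -0.57 (-1.21), liver against brain hybrid departure was 514 (1793), muscle against brain hybrid departure was 1685 (3540), muscle against liver hybrid departure was 1055 (5491), liver LPC against LCP, liver-enriched median against the rest was -0.023 (0.008), muscle hybrids against mid-parent evm.model.Chr1.830 was 0 (-0.86). With median-ratio scaling, brain LCP against mid-parent was 5 (2), liver LCP against LP was 849 (4193), liver LCP against LC was 774 (4152), liver LPC against LCP was 19 (30), liver LPC against mid-parent was 387 (696), liver LCP against mid-parent was 499 (5098), liver hybrids against mid-parent was 938 (4080), muscle LC against LP was 2508 (5591), muscle LPC against LC was 3555 (6883), muscle LPC against LCP was 111 (518), muscle LPC against mid-parent was 2741 (5309), liver LCP outside both parents was 143 (1849), muscle LPC outside both parents was 700 (1371), liver LPC position was -0.12 (-0.17), liver LCP position was 0.017 (-0.092), muscle LPC position was -0.63 (-1.21), liver against brain hybrid departure was 430 (1793), muscle against brain hybrid departure was 1861 (3540), muscle against liver hybrid departure was 1314 (5491), liver LPC against LCP, liver-enriched median against the rest was -0.11 (0.008). With a linear mid-parent, brain LCP against mid-parent was 4 (2). With a shift to a common median, liver LCP against LP was 792 (4193), liver LCP against LC was 874 (4152), liver LPC against LCP was 16 (30), liver LPC against mid-parent was 417 (696), liver LCP against mid-parent was 488 (5098), liver hybrids against mid-parent was 932 (4080), muscle LC against LP was 2740 (5591), muscle LPC against LCP was 219 (518), muscle LCP against mid-parent was 4537 (2974). Over IDs with a parental log2 difference of at least 1, liver LPC position was -0.14 (-0.17), liver LCP position was -0.064 (-0.092). With same-numbered libraries paired across tissues, liver against brain hybrid departure was 908 (1793).

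Quantile normalization gives the top-ranked ID 1 value in all libraries, so the value of evm.model.Chr1.830 is 0 by construction. Covariate values in brain have p-values that are too small, since the component came from the same data; it held 39.6% of the residual variance, and replicate 1 lay below 0 and replicate 2 above 0 in all 4 crosses. Not every same-numbered pair of different crosses had a correlation over 0.1, so numbers were not taken as pairs within a tissue. In brain, though, 10 of 18 such pairs did (median 0.223), against 10 of 36 others (median -0.076), so brain libraries of 1 number tended to deviate together. In liver it was 2 of 18 against 4 of 36, and in muscle 4 of 18 against 7 of 36. The block moved no other count of calls by over 1.5 times. With it, muscle-enriched IDs in LPC against LCP muscle had a camera adjusted p of 0.0576 (0.0255) with an estimated correlation, so that this call was lost. Across tissues, 33 of 36 same-numbered pairs of a cross were over 0.1, short of all, against 0 of 72 others. Deviations of 3 libraries from their mean sum to 0, so positive correlations of same-numbered pairs push the others below 0. The others are therefore no separate comparison, here or within a tissue.

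With 1 library left out, a cross has 2 libraries and shares the spread of the others. Brain top-10 share, hybrids against parents ranged from 0.88 to 1.76. Liver top-10 share, hybrids against parents ranged from 10.3 to 14. Muscle top-10 share, hybrids against parents ranged from -13.9 to -10.5. Brain LC against LP ranged from 262 to 513 (without LP 1 262, without LP 3 276, without LC 1 358, without LC 2 310, without LC 3 277). Brain LPC against LP ranged from 34 to 99 (without LP 1 53, without LP 3 34, without LPC 1 55, without LPC 2 41). Brain LPC against LC ranged from 21 to 32 (without LC 1 21, without LPC 2 24, without LPC 3 26). Brain LCP against LP ranged from 44 to 63 (without LP 1 47, without LP 3 47, without LCP 1 57, without LCP 2 47, without LCP 3 44). Brain LCP against LC ranged from 19 to 30 (without LCP 3 19). Brain LPC against LCP ranged from 0 to 4 (without LPC 2 2, without LPC 3 4, without LCP 2 2). Brain LPC against mid-parent ranged from 1 to 9 (without LP 1 3, without LP 3 3, without LC 1 2, without LC 2 4, without LC 3 1, without LPC 1 4, without LPC 2 2, without LPC 3 3). Brain LCP against mid-parent ranged from 1 to 7 (without LP 2 5, without LP 3 7, without LC 2 1, without LC 3 1, without LCP 1 1, without LCP 3 1). Brain hybrids against mid-parent ranged from 2 to 13 (without LP 1 5, without LC 1 5, without LC 2 2, without LCP 2 4, without LCP 3 4). Liver LC against LP ranged from 1316 to 1723. Liver LPC against LP ranged from 298 to 535 (without LP 1 507, without LP 2 535, without LP 3 298, without LPC 1 528, without LPC 2 323, without LPC 3 315). Liver LPC against LC ranged from 580 to 1574 (without LC 1 580, without LPC 2 592, without LPC 3 703). Liver LCP against LP ranged from 2143 to 3283 (without LP 1 2753, without LP 3 2295, without LCP 1 2143, without LCP 2 2659, without LCP 3 2701). Liver LCP against LC ranged from 2235 to 4241 (without LC 1 2235, without LCP 1 2276). Liver LPC against LCP ranged from 10 to 18 (without LPC 1 16, without LPC 2 10, without LPC 3 18, without LCP 1 12, without LCP 2 13, without LCP 3 13). Liver LPC against mid-parent ranged from 107 to 1223 (without LP 3 330, without LC 1 298, without LC 2 1223, without LPC 1 268, without LPC 2 107, without LPC 3 176). Liver LCP against mid-parent ranged from 2251 to 5337 (without LCP 1 2251, without LCP 2 3135, without LCP 3 3108). Liver hybrids against mid-parent ranged from 2766 to 4383. Muscle LC against LP ranged from 4041 to 5662. Muscle LPC against LP ranged from 550 to 1616 (without LP 3 851, without LPC 2 568, without LPC 3 550). Muscle LPC against LC ranged from 5732 to 6707. Muscle LCP against LP ranged from 730 to 1716 (without LP 2 730, without LCP 1 1017, without LCP 3 1059). Muscle LCP against LC ranged from 3291 to 4787. Muscle LPC against LCP ranged from 54 to 1184 (without LPC 2 66, without LPC 3 54, without LCP 1 189, without LCP 2 132, without LCP 3 1184). Muscle LPC against mid-parent ranged from 3625 to 5410. Muscle LCP against mid-parent ranged from 1339 to 3265 (without LCP 3 1339). Muscle hybrids against mid-parent ranged from 4268 to 5324. Brain LPC outside both parents ranged from 0 to 4 (without LP 1 1, without LP 3 0, without LC 1 0, without LC 2 1, without LC 3 0, without LPC 2 1). Brain LCP outside both parents ranged from 0 to 1 (without LC 1 1, without LC 2 1). Liver LPC outside both parents ranged from 53 to 286 (without LP 3 61, without LC 1 80, without LC 2 286, without LPC 2 53, without LPC 3 61). Liver LCP outside both parents ranged from 668 to 2153 (without LP 3 1030, without LC 1 990, without LCP 1 668, without LCP 2 1007, without LCP 3 991). Muscle LPC outside both parents ranged from 398 to 1304 (without LP 3 561, without LPC 2 400, without LPC 3 398). Muscle LCP outside both parents ranged from 249 to 705 (without LP 2 291, without LP 3 345, without LCP 3 249). Brain LPC position ranged from 0.050 to 0.34 (without LP 2 0.34, without LC 3 0.056, without LPC 1 0.050). Brain LCP position ranged from 0.13 to 0.24. Liver LPC position ranged from -0.32 to -0.052 (without LP 1 -0.053, without LP 2 -0.052, without LC 1 -0.069, without LC 2 -0.28, without LC 3 -0.32, without LPC 2 -0.14). Liver LCP position ranged from -0.35 to 0.11 (without LP 1 -0.036, without LP 2 0.11, without LP 3 -0.13, without LC 1 0.034, without LC 2 -0.31, without LC 3 -0.35). Muscle LPC position ranged from -1.33 to -1.05. Muscle LCP position ranged from -0.76 to -0.32. Liver against brain hybrid departure ranged from 1250 to 2214. Muscle against brain hybrid departure ranged from 2891 to 3818. Muscle against liver hybrid departure ranged from 5040 to 5530.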

Other observations

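The test of abundance-matched IDs and of the side of their calls was fixed before its result was seen, and the tests of replicate numbers across tissues, the scalings set beside it and the splits for ID groups in brain and for liver-enriched IDs in muscle were chosen after. Some IDs were present in 1 parental species and not in the other, here taken as an FPKM of at least 2 in all 3 libraries of 1 species and at most 0.1 in all 3 of the other, a definition chosen after the values were seen. In brain, 48 IDs were present in LC alone and 27 in LP alone, in liver 33 and 42, and in muscle 16 and 26. Of these, 31 and 21 in brain, 24 and 34 in liver, and 10 and 24 in muscle started with BGI_novel. Of all 24212 IDs in the table, 2782 did. Whether a value near 0 reflects absence or poorer alignment of the reads of that species was not tested. Of the IDs present in 1 species alone, both hybrids listed 28 and 8 in brain, 6 and 18 in liver, and 8 and 21 in muscle at an FPKM of at least 0.5 in every library. BGI_novel_G002127 was in LC and LCP and listed at 0 in LP and LPC in all 3 tissues, with brain levels of 12.6 ± 9.57 in LC and 11.8 ± 6.85 in LCP (SD, n = 3 each).

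IDs starting with BGI_novel were called between LC and LP more often than EVM IDs in brain and liver, 14.0% against 2.35% and 33.5% against 13.6% as deposited and 14.0% against 2.43% and 30.2% against 12.3% after scaling. In muscle they were called less often as deposited (47.4% against 51.9%) and more often after scaling (38.1% against 21.8%), and within bins of like mean FPKM the ratio of called shares went from 0.977 to 1.82, so no cause can be weighed there, nor from the 45.2% of called ones that were higher in LC after scaling. Within such bins the ratio after scaling was 6.44 in brain and 2.57 in liver, and 6.30 and 2.52 as deposited, which argues against lower abundance as the cause in these tissues. Of the called ones, 55.2% in brain and 43.5% in liver were higher in LC after scaling, beside 66.2% and 48.5% of EVM IDs (48.2% and 53.5% as deposited), so poorer alignment of the reads of 1 species and a real difference cannot be told apart, since models made from both species would put calls on both sides, and how these gene models were made is not given in the sources used here. Poorer alignment and a real difference between the species stay open.

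Libraries of different tissues with the same replicate number deviated together within a cross. In 4 of 4 crosses the labelled numbering had the highest mean correlation across IDs among 36 assignments, 0.195 in LP, 0.218 in LC, 0.143 in LPC and 0.181 in LCP, against highest other values of 0.093, 0.118, 0.09 and 0.101. This is in line with same-numbered libraries coming from the same fish, which the labels do not state. A batch shared across crosses is argued against, for all 3 tissues at once, by the lowest tissue median of correlations between same-numbered libraries of different crosses, -0.013. In brain that median was 0.223, so a batch in brain alone stays open.

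Other splits of the same libraries were counted for each fit, and each count of splits includes the real one. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and only the real and highest other counts are given. For LC against LP they were 613 and 1 in brain, 1957 and 4 in liver, and 5591 and 0 in muscle. For LPC against LP they were 97 and 3, 827 and 1, and 1819 and 2. For LPC against LC they were 41 and 1, 1307 and 5, and 6883 and 3. For LCP against LP they were 91 and 551, 4193 and 1, and 1738 and 0, and in brain 1 split besides the real one gave as many, 2 in all. For LCP against LC they were 29 and 3, 4152 and 3, and 4625 and 1, and for LPC against LCP 0 and 4, 30 and 2, and 518 and 5. The split with 551 set LP 1, LP 3 and LCP 1 against LP 2, LCP 2 and LCP 3, and this many calls point to a structure of the brain samples.

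Against the mid-parent, 100 splits were drawn. They mix libraries of LP, LC and the hybrids. The difference between the species then enters the spread of other splits and can lower their counts. A share under 0.05 therefore speaks against all crosses being alike. It does not test the departure from the mid-parent by itself. The share was under 0.05 for the mean of the hybrids in liver and muscle. Real and highest other counts were 4080 and 545 in liver and 5119 and 1286 in muscle (1 split in each, the real one). It was also under 0.05 for LCP in liver (5098 and 3272) and for LPC and LCP in muscle (5309 and 3248, 2974 and 1240), with 1 split each. For LPC in liver (696 and 1262) it was under 0.05 with 2 splits. For IDs outside both parents it was under 0.05 for LPC in liver (148 and 405), with 3 splits. The same held for LCP in liver (1849 and 906), LPC in muscle (1371 and 595) and LCP in muscle (603 and 347), with 1 each. In brain the share was under 0.05 for the mean of the hybrids (9 and 7, 1 split), which had 9 calls with the replicate number as a block too. No splits were drawn with the block, and the 9 became 2 without LC 2, so chance is not taken as excluded there. The share was also under 0.05 for LPC against the mid-parent (7 and 69, 2 splits) and for LPC outside both parents (3 and 24, 3 splits). The splits take no account of replicate numbers, although brain libraries of 1 number tended to deviate together, and with the block the 7 became 1 and the 3 became 2, so chance is not taken as excluded for LPC in brain. It cannot be excluded for LCP in brain, where 12 splits gave as many against the mid-parent (2 and 1182). Outside both parents its real count was 0, which every split reaches by construction, so no conclusion is drawn (highest other 179). The split with 69 set the 3 LC libraries against mixed LP and LPC libraries and so holds the difference between the species, while that with 1182 and 179 mixed all 3 crosses and points to a structure of the brain samples.

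For the medians of ID groups against the other IDs, the absolute real and highest other values are given. In muscle, against the mid-parent, 1 of 100 splits gave as much for broad (0.376 and 0.227) and brain-enriched IDs (0.24 and 0.151). The same held for liver-enriched IDs in muscle (0.293 and 0.227). In liver, 2 splits did for brain-enriched IDs (0.068 and 0.071). These shares are under 0.05, but the splits mix the crosses here too and speak only against all crosses being alike. As deposited, the camera test did not call these groups with an estimated correlation (adjusted p = 0.5 for each in muscle and 0.381 in liver), and liver-enriched IDs in muscle were not called at the preset correlation after scaling (adjusted p = 0.0507). Chance cannot be excluded for liver-enriched IDs in liver (0.058 and 0.156), where 47 splits gave as much. Nor can it for broad IDs in brain (0.13 and 0.183, 17 splits) and brain-enriched IDs in brain (0.155 and 0.232, 22 splits). For muscle-enriched IDs in muscle, with 10 splits, the values were 0.215 and 0.278 for LC against LP and 0.371 and 0.276 for LPC against LCP.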
